A study of Mus musculus with 18 samples.

How the data were processed

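Total RNA of sorted mouse T cells was hybridised to Affymetrix arrays. Per the labels, cells came from mice of 6 to 8 weeks, were enriched by positive selection of CD4 cells on beads and double sorted on GFP, and RNA was extracted with Trizol and labelled with biotin. The labels give 18 arrays in 6 groups: 5 Treg and 5 Teff arrays from spleen and lymph nodes of DT-treated Foxp3DTR mice, and 2 arrays each of Treg and Teff from spleen and lymph nodes and from B16 tumours of Foxp3GFP mice. The titles call the Treg cells of DT-treated mice aTreg. Groups and replicate numbers were taken from the labels and titles. The labels do not say which animal, litter or day a replicate comes from, nor the time between treatment and harvest, the sex of the mice or the array dates, and these are not given in the sources used here.

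The deposited values are log2 expression values made by the authors with RMA (background correction, quantile normalization and summary per probe set), per the submitters' processing notes, which do not give the RMA version. They come as 1 value table of 10 arrays with 45101 probe sets and 1 of 8 arrays with 22690 probe sets. No scanner intensities were used here. The medians of the arrays lay within 4.05 to 4.14 in the larger table and within 5.87 to 5.9 in the smaller one, so no further scaling was applied. The series also holds a table of the larger array with 21 value columns. 5 of them matched the Treg arrays of DT-treated mice within 5e-09, and the other 16, which could not be matched to a sample, were not used.

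Probe sets were named from the gene columns of the deposited table, with symbols updated through the RefSeq gene table of assembly GRCm38.p6, used for names only. Of the probe sets on the 10 arrays, 31995 had a current symbol, 540 were named by accession, 2978 by synonym, 2956 kept the deposited name and 6632 had no single name. On the 8 arrays these numbers were 19514, 540, 1160, 396 and 1080. A gene was represented by the probe set with the highest mean over all arrays of its table among those with exactly 1 symbol, which gave 20792 and 13231 genes. The probe set of a gene could thus differ between the tables, as for Itgae, Ikzf2, Cd8a and Xist. No filter on dim genes was applied. The annotation release behind the deposited names is not given in the sources used here.

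Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, on log2 values without replicate block or covariates, with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p under 0.05. The DT groups were fitted alone. The other 4 groups were fitted together, with 1 coefficient per group and a shared estimate of the spread, and gave 4 contrasts of 2 groups and the interaction (tumour Treg minus tumour Teff) minus (spleen Treg minus spleen Teff). The median standard error of a gene was 0.134 in DT-treated mice, 0.106 in the comparisons of 2 arrays with 2 and 0.15 in the interaction. Every adjusted p in the text comes from limma. Calls of separate comparisons were set beside n1 × n2 / N, the number that independent lists would share, per direction. Foxp3 in DT-treated mice was also tested with an exact two-sided permutation test. Figures were drawn with matplotlib 3.10.9, and names were joined with pandas 2.3.3 in Python 3.11.15.

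Design, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The 28 lists were drawn from textbook knowledge: Treg core, conventional T, effector Treg, naive and lymphoid homing, inhibitory receptors, costimulatory TNF receptor family, Th1, Th2, Th17, Tfh, cell cycle, interferon response, chemokine receptors, T cell receptor early response, glycolysis and hypoxia, Polycomb and DNA methylation, heat shock and stress, and cytotoxic effector. Marker lists covered T cells, CD8 T cells, B cells, plasma cells, macrophages and dendritic cells, neutrophils, NK cells, melanoma cells, stromal and endothelial cells, and erythroid cells. Some lists share genes, such as Tcf7 in the conventional T and the naive and lymphoid homing lists, so their results are not independent. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01 and again with a correlation estimated per list, with adjustment over the lists of 1 comparison. In the latter setting camera also refers the test to the residual degrees of freedom, 8 in DT-treated mice and 4 in the other comparisons. A call lost there need not come from correlated members. A further list of plasmacytoid dendritic cell genes was written after the tumour values had been seen and before its own test. Members passing the test are counted with adjustment over all genes and adjusted over the list alone.

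The rule for named genes took Foxp3 first. Per comparison it then took, among genes with adjusted p under 0.05 whose groups did not overlap, the 10 largest rises and the 10 largest falls. For the interaction it took 6 each, by adjusted p alone. Symbols that start with Gm and a digit or with LOC or end in Rik, and segments of immunoglobulin and T cell receptor genes, were left out. From each list it took up to 4 members with the largest absolute difference. A few genes the rule allows are not reported here by name, though they count in their lists. Genes named outside this rule are said to have been chosen after their values were seen.

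The fits were tested on simulated data with the real gene means and spreads, with 100 genes changed by 0.5 log2 and 100 by 1 log2. In DT-treated mice 28 and 81 of each 100 were called, with 10 of 20592 unchanged genes called. In the spleen contrast 34 and 78 were called (10 of 13031 unchanged genes), in the tumour contrast 39 and 85 (4 unchanged), in the Treg tissue contrast 38 and 86 (10 unchanged) and in the Teff tissue contrast 35 and 78 (5 unchanged). In the interaction 1 and 58 were called (3 unchanged), so that most differences of 0.5 log2 went unseen in that simulation. In each real fit more genes passed than were changed here. The adjustment is then less strict, so these shares need not carry over to the real data.

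Alternatives to each fit were the mean of a gene's probe sets, all probe sets, probe sets without the cross-hybridising _x_at and _s_at kinds, a filter on dim genes, renewed quantile normalization, centring on medians, eBayes with trend and robust, array weights, the replicate number as a block, only the 4 compared arrays, and leaving out each array in turn. Overlaps were recounted at adjusted p under 0.01. Leaving out the DT arrays numbered 4, and these with Teff array 5, was added after seeing the data.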

Results

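Gene expression was measured in sorted mouse CD4 T cells on 18 Affymetrix arrays that fall into 6 groups. Cells labelled Treg (regulatory T cells) were sorted as positive, and cells labelled Teff as negative, for Foxp3, the transcription factor that defines the Treg lineage. 10 arrays, 5 labelled Treg and 5 labelled Teff, came from spleen and lymph nodes of Foxp3DTR mice treated with DT. In such mice the receptor for diphtheria toxin is made under control of Foxp3, so that the toxin removes Treg cells. The other 8 arrays came from mice of the strain Foxp3GFP, whose Foxp3-expressing cells carry a green fluorescent protein. They comprise 2 Treg and 2 Teff arrays from spleen and lymph nodes and 2 Treg and 2 Teff arrays from tumours of B16, a mouse melanoma line. The deposited log2 values had array medians from 4.05 to 4.14 in the table of 10 arrays and from 5.87 to 5.9 in the table of 8. The 2 tables hold different numbers of probe sets and were normalized separately, so they were set side by side only through differences made within each table. The number of arrays limits the precision, and the labels do not say whether replicates are separate animals, so every p-value measures only the spread between these samples. The rule for named genes takes the largest rises and falls only where the arrays of the 2 groups do not overlap, so that separation is no further evidence for them.

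Foxp3 itself was called between Treg and Teff arrays in spleen and lymph node of Foxp3GFP mice and in no other setting. Its probe set (1420765_a_at) read 9.97 ± 0.029 (SD, n = 2) in those Treg arrays and 3.12 ± 0.10 (SD, n = 2) in the Teff arrays, a log2 difference of 6.85 (SE 0.088, adjusted p = 8.54e-09). In DT-treated mice it read 3.22 ± 0.127 (SD, n = 5) in arrays labelled Treg and 3.19 ± 0.181 (SD, n = 5) in arrays labelled Teff. The difference of 0.025 was smaller than the spread between arrays, and an exact two-sided permutation test over 252 splits gave p = 0.778. In the tumour the arrays labelled Treg read 3.25 ± 0.074 (SD, n = 2) and those labelled Teff 3.15 ± 0.036 (SD, n = 2; difference 0.10, adjusted p = 0.481). Foxp3 thus went against the label in 7 arrays labelled Treg, and "Treg" stands for that label throughout. Other genes of the Treg core list did follow the label. Ctla4, an inhibitory receptor, differed by 3.08 in DT-treated mice, 2.23 in spleen and lymph node and 2.03 in the tumour. Il2ra, the high-affinity chain of the interleukin-2 receptor, differed by 4.04, 4.64 and 4.25. Sex-linked transcripts differed within the table of 8 arrays, in Treg and Teff arrays alike. Xist (1427262_at), which is transcribed from the inactive X chromosome of females, read at most 2.62 and the Y-linked Ddx3y at least 9.9 on the 4 tumour arrays. On the 4 arrays from spleen and lymph node, Xist read at least 10.57 and Ddx3y at most 2.81. The Teff arrays among them had low Foxp3, having been sorted as negative for it. In the table of 10 arrays Xist is represented by another probe set, which read at most 2.31, and Ddx3y read at least 7.24.

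**Figure D1:**
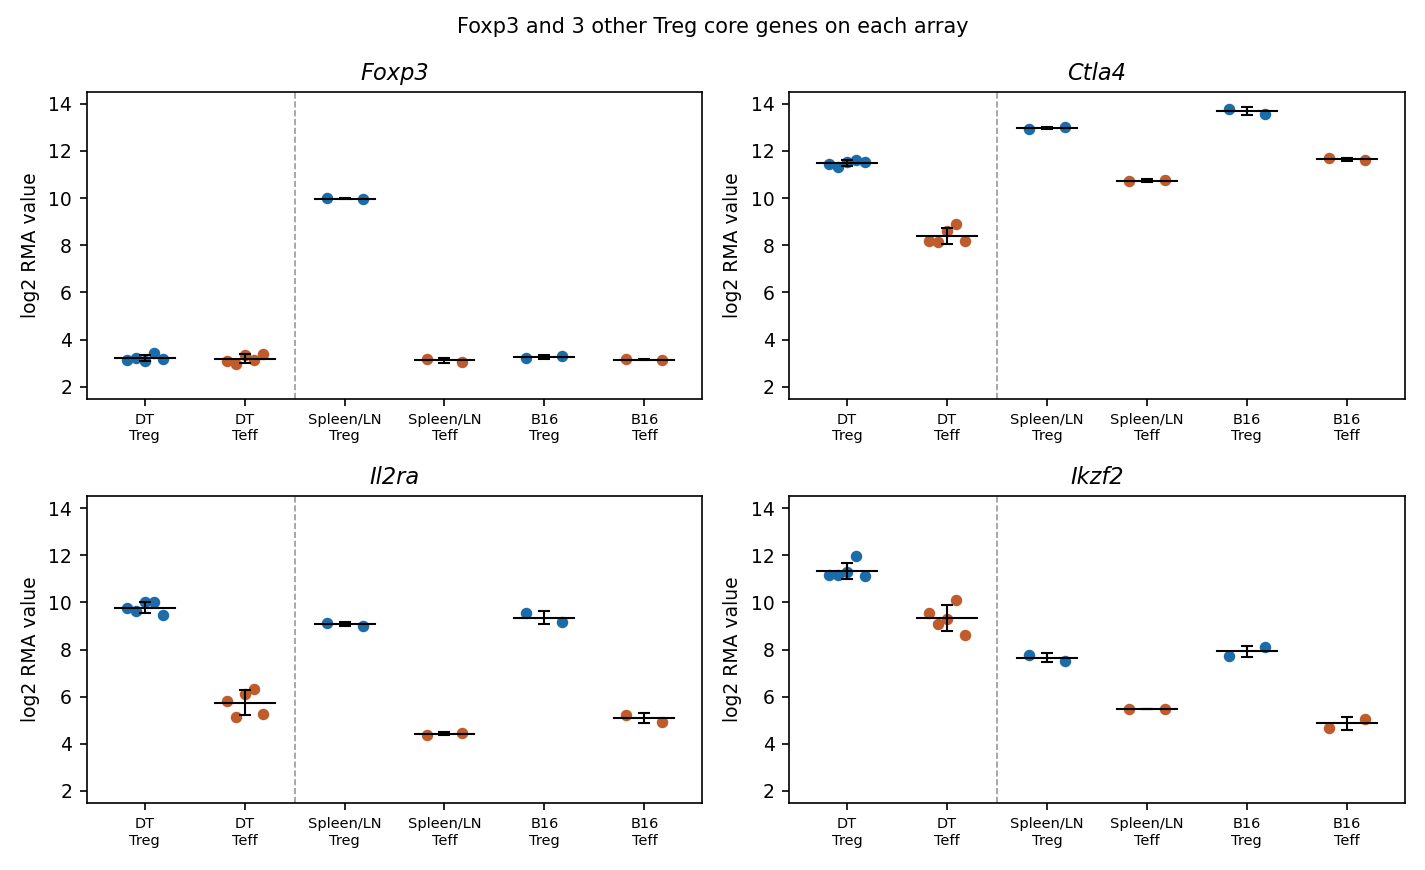
Log2 RMA values (y axis) of Foxp3, Ctla4, Il2ra and Ikzf2 on each array, by group (x axis); points are arrays, horizontal lines group means, bars the SD, and the dashed line parts the 2 separately normalized tables. Foxp3 reached 9.97 in the spleen and lymph node Treg arrays and had group means from 3.12 to 3.25 elsewhere, while the other 3 genes were higher in Treg than in Teff arrays of each setting.

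The first comparison asked how Treg cells differ from Teff cells in DT-treated mice, in which the loss of Treg cells brings on inflammation. Treg core, effector Treg and cell cycle genes were higher in Treg arrays, and conventional T and Tfh genes were lower. Il2ra (1420692_at) read 9.78 ± 0.229 (SD, n = 5) against 5.74 ± 0.52 (SD, n = 5), a log2 difference of 4.04 (SE 0.217, adjusted p = 1.26e-07). Klrg1 (1420788_at), an inhibitory receptor of highly differentiated lymphocytes, was higher by 3.78 (SE 0.151, adjusted p = 2.17e-08), and Gzmb (1419060_at), the protease granzyme B, by 3.68 (SE 0.21, adjusted p = 1.97e-07). Sostdc1 (1449340_at), a secreted antagonist of bone morphogenetic proteins, read 3.66 ± 0.356 (SD, n = 5) against 9.10 ± 0.213 (SD, n = 5) and was thus lower, at -5.44 (SE 0.167, adjusted p = 2.56e-09). Il21 (1450334_at), a cytokine of follicular helper cells, differed by -3.99 (SE 0.167, adjusted p = 2.43e-08). Klrd1, the CD94 chain of natural killer receptors, differed by -4.52, Il4 by -3.72 and Il2 by -3.31. The Treg means of Sostdc1, Il21, Klrd1 and Il2 lay below the median of every array, so background limits what the sizes of these differences say.

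By list, 20 of the 24 measured Treg core genes were higher in DT Treg arrays, 0 were lower and 4 did not pass (20 higher adjusted over the list alone). The list's median log2 difference was 1.74 (camera adjusted p = 4.81e-31), with Il2ra, Klrg1, Socs2 (3.17) and Ctla4 in the lead. Of 22 effector Treg genes, 18 were higher and 1 was lower (19 and 1 adjusted over the list alone, median 1.09, adjusted p = 5.09e-19). They included Gzmb and Itgae (2.24), the integrin that binds E-cadherin. Of 13 conventional T genes, 12 were lower, 13 adjusted over the list alone (median -1.50, adjusted p = 3.94e-24), including Pde3b (-3.02), Dapl1 (-2.71) and Tcf7 (-2.52). The Tfh list had 7 lower and 1 higher of 11 (the same counts adjusted over the list alone, median -1.46, adjusted p = 2.82e-09). Its lower genes included Tox2 (-3.37), Bcl6 (-2.39), the transcription factor of follicular helper cells, and Pdcd1 (-1.73). Cell cycle genes moved together: 28 of 32 were higher and 0 lower, 31 higher adjusted over the list alone (median 1.38, adjusted p = 6.14e-27). The kinases Aurkb (1.96), Bub1 (1.64) and Cdk1 (1.63), which drive or check mitosis, are examples. Those 5 lists and the NK cell markers were also called with an estimated correlation, at adjusted p = 2.1e-04, 0.00941, 0.00291, 0.00693, 0.0436 and 0.0436. The NK cell markers had 2 of 5 lower (2 adjusted over the list alone, median -0.24, adjusted p = 0.00298), among them Eomes (-1.58) and Klrb1c (-1.10).

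7 further lists were called with the preset correlation only. Naive and lymphoid homing genes had 8 lower and 1 higher of 14 (10 and 1 adjusted over the list alone, median -0.96, adjusted p = 9.6e-09, adjusted p = 0.0932 with an estimated correlation). Glycolysis and hypoxia genes had 9 higher and 1 lower of 21 (11 and 3 adjusted over the list alone, median 0.36, adjusted p = 2.6e-04, adjusted p = 0.272 with an estimated correlation). P4ha1 was higher by 1.65 and the glucose transporter Slc2a3 by 1.35, and Pdk1 differed by -1.13. Among costimulatory TNF receptors 5 of 9 were higher and 2 lower (5 and 3 adjusted over the list alone, adjusted p = 0.0079, adjusted p = 0.281 with an estimated correlation). Tnfrsf9 (2.48), Tnfrsf1b (2.17) and Tnfrsf4 (1.86) led them. Among chemokine receptors 8 of 14 were higher and 2 lower (8 and 4 adjusted over the list alone, adjusted p = 0.0256, adjusted p = 0.253 with an estimated correlation), with Ccr3 (2.11) and Ccr8 (1.65) higher and Cxcr6 (-2.53) lower. Cytotoxic effector genes split. Gzmb and Gzmc (2.24) were higher, and 5 of 11 were lower, such as Gzmk (-3.05) and Fasl (-1.51). Adjusted over the list alone 2 were higher and 7 lower (median -0.54, adjusted p = 0.00414, adjusted p = 0.281 with an estimated correlation). The Th1 list had 5 lower and 2 higher of 15 (6 and 2 adjusted over the list alone, median -0.27, adjusted p = 0.0366), for example Ccl5 at -1.90. The neutrophil markers had Mmp9 (3.02) higher and 7 of 8 not passing (1 higher adjusted over the list alone, median 0.16, adjusted p = 0.0395). Both had adjusted p = 0.281 with an estimated correlation and 0.0502 with the replicate number as a block, which ended their calls.

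The other 15 lists were not called in DT-treated mice (adjusted p from 0.159 to 0.985). Polycomb and DNA methylation genes, the group nearest to the chromatin theme of the series, had 3 higher and 1 lower of 18 (the same counts adjusted over the list alone, median -0.03, adjusted p = 0.985), with Uhrf1, which maintains DNA methylation at replication, at 1.43. Of these 4 calls, that of Ezh2 (0.74, adjusted p = 0.0341) ended without any 1 of 6 arrays and that of Ezh1 (-0.61, adjusted p = 0.0171) without any 1 of 2. Without Treg array 3 both ended (adjusted p = 0.0955 and 0.0547), and with the mean of probe sets Ezh1 had adjusted p = 0.172. Plasma cell markers had 0 of 4 passing (1 higher adjusted over the list alone, adjusted p = 0.985) and erythroid markers 0 of 5 (0 adjusted over the list alone, adjusted p = 0.889). B cell markers went both ways, with Cd79b at 1.64 and Cd22 at -2.15 (2 higher and 4 lower of 12, also adjusted over the list alone, adjusted p = 0.159). Macrophage and dendritic cell markers had 1 higher and 3 lower of 15 (also adjusted over the list alone, adjusted p = 0.985). Tyrobp differed by -1.73 (adjusted p = 0.00689), H2-Aa of the B cell list by -1.68 (adjusted p = 0.0256) and Fcer1g by -1.08 (adjusted p = 0.0356). The call of H2-Aa ended without any 1 of 5 arrays and that of Fcer1g without any 1 of 6 (highest adjusted p over all alternatives 0.0753 and 0.0933). Cd8a differed by 0.079 and Cd4 by -0.37 (adjusted p = 0.874 and 0.076). The median, the mean and the direction of the test differed in sign for the inhibitory receptor, Th17, interferon, Polycomb, CD8, plasma cell and macrophage and dendritic cell lists, none of them called. In all, 2187 of 20792 genes passed limma's test, 1239 higher and 948 lower in Treg arrays, of which 685 differed at least 2-fold (4364 at an unadjusted p under 0.05). Treg array 4 and Teff arrays 4 and 5 correlated less with their own groups (mean r 0.981, 0.972 and 0.977) than the other 7, and without these 3 arrays 3644 genes passed. Hba-a1, a haemoglobin chain, read 8.37 and 7.37 on the arrays numbered 4.

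In spleen and lymph node of Foxp3GFP mice the same contrast asked how Treg and Teff cells differ without DT. Besides Foxp3, Itgae (1449216_at) was higher in Treg arrays, at 9.38 ± 0.077 (SD, n = 2) against 4.39 ± 0.091 (SD, n = 2), a log2 difference of 4.99 (SE 0.229, adjusted p = 7.26e-06). Il2ra was higher by 4.64 (SE 0.145, adjusted p = 2.17e-06) and Gpr83 (1423415_at), an orphan receptor of Treg cells, by 4.12 (SE 0.151, adjusted p = 3.37e-06). Lower in Treg arrays were Il21 (1450334_at), at 4.65 ± 0.012 (SD, n = 2) against 8.75 ± 0.025 (SD, n = 2; difference -4.09, SE 0.193, adjusted p = 8.93e-06), and Spp1 (1449254_at), the cytokine osteopontin, at -4.30 (SE 0.397, adjusted p = 2.29e-04). Klrd1 differed by -3.85, Gzmk by -3.22 and Il2 by -2.51.

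23 of 24 Treg core genes were higher (24 adjusted over the list alone, median 2.28, adjusted p = 3.4e-36), and all 11 conventional T genes were lower (11 adjusted over the list alone, median -1.66, adjusted p = 2.35e-14), such as Igfbp4 (-2.74), Tnfsf8 (-2.11) and the transcription factor Lef1 (-1.66). These 2 of the 12 called lists were also called with an estimated correlation, at adjusted p = 0.0118 and 0.016. Effector Treg genes had 18 higher and 0 lower of 22 (19 and 0 adjusted over the list alone, median 1.68, adjusted p = 3.79e-20, adjusted p = 0.0797 with an estimated correlation). They included Fgl2 (3.60), Areg (2.89), a growth factor of tissue repair, and Il1rl1 (2.82), the receptor of interleukin-33. Th2 genes had 7 higher and 1 lower of 10 (7 and 1 adjusted over the list alone, median 0.87, adjusted p = 3.07e-04, adjusted p = 0.0833 with an estimated correlation). Areg, Il1rl1 and Il10 (2.45) were higher and Il4 was lower (-2.32). Th1 genes had 9 lower and 1 higher of 15 (11 and 1 adjusted over the list alone, median -0.63, adjusted p = 1.56e-05, adjusted p = 0.213 with an estimated correlation). Ifng differed by -2.30, Fasl by -2.26 and Ccl3 by -2.03. Cytotoxic effector genes had 6 lower and 2 higher of 11 (7 and 3 adjusted over the list alone, adjusted p = 0.00577, adjusted p = 0.213 with an estimated correlation). Cell cycle genes had 17 higher and 0 lower of 32 (21 and 0 adjusted over the list alone, median 0.49, adjusted p = 1.13e-11, adjusted p = 0.125 with an estimated correlation). Tk1 (1.4) and Mki67 (0.97), both active in dividing cells, were among them. Naive and lymphoid homing genes had 10 lower and 1 higher of 13 (the same adjusted over the list alone, median -1.18, adjusted p = 4.3e-09, adjusted p = 0.0664 with an estimated correlation).

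The remaining 4 called lists were higher. Costimulatory TNF receptors had 5 higher and 1 lower of 9 (the same adjusted over the list alone, median 0.87, adjusted p = 3.07e-04), led by Tnfrsf9 (2.79) and Tnfrsf4 (2.64). Chemokine receptors had 7 higher and 2 lower of 14 (the same adjusted over the list alone, median 0.38, adjusted p = 0.00944), with Ccr6 (2.5) and Ccr2 (2.24) higher and Cxcr6 (-3.12) lower. Both had adjusted p = 0.125 with an estimated correlation. Inhibitory receptors had 2 higher of 9 (2 adjusted over the list alone, median 0.25, adjusted p = 0.0109, adjusted p = 0.128 with an estimated correlation), Ctla4 and Entpd1 (1.75). Th17 genes had 4 higher and 1 lower of 7 (4 and 2 adjusted over the list alone, adjusted p = 0.0467, adjusted p = 0.209 with an estimated correlation). Their call also ended with the replicate number as a block (adjusted p = 0.0541). The 16 lists not called had adjusted p from 0.0708 to 0.994, among them melanoma (0 of 9 passing, also adjusted over the list alone) and stromal markers (0 of 10 passing, also adjusted over the list alone). Macrophage and dendritic cell markers had 3 higher and 2 lower of 15 (also adjusted over the list alone, median 0.32, adjusted p = 0.285). Tyrobp, an adaptor of myeloid and natural killer receptors, was at -2.0, while Lyz2 read 9.60 and 9.88 in Treg against 8.07 and 8.28 in Teff arrays. Plasmacytoid dendritic cell genes, listed after the tumour values were seen, had 9 lower and 0 higher of 12 (median -1.22, adjusted p = 4.32e-05, adjusted p = 0.428 with an estimated correlation). The uncalled Tfh, Polycomb, T cell, plasma cell and neutrophil lists had a median, mean and test direction that did not share 1 sign. In all 1832 of 13231 genes passed, 985 higher and 847 lower, 433 of them at least 2-fold (3470 at an unadjusted p under 0.05). Without Teff array 1 the count was 1080, and without Teff array 2 it was 969.

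In B16 tumours the contrast asked how Treg cells in a tumour differ from Teff cells there. Treg core genes were higher in tumour Treg arrays, and conventional T and naive and lymphoid homing genes were lower. Klrg1 (1420788_at) read 10.97 ± 0.358 (SD, n = 2) against 6.14 ± 0.139 (SD, n = 2), a log2 difference of 4.84 (SE 0.18, adjusted p = 2.55e-06). Areg (1421134_at) was higher by 3.99 (SE 0.251, adjusted p = 1.99e-05) and Havcr2 (1451584_at), the inhibitory receptor TIM-3, by 3.93 (SE 0.23, adjusted p = 1.53e-05). Tcf7 (1433471_at), a transcription factor of naive and memory T cells, read 7.32 ± 0.118 (SD, n = 2) against 11.63 ± 0.083 (SD, n = 2) and was lower, at -4.31 (SE 0.105, adjusted p = 7.38e-07). Ccr9 (1427419_x_at), a homing receptor, differed by -6.12 (SE 0.514, adjusted p = 8.43e-05) and Tyrobp (1450792_at) by -4.94 (SE 0.283, adjusted p = 1.42e-05). Klrd1 (-5.49), Mpeg1 (-5.27), Ly6d (-5.00) and Cdh1 (-4.94) were also lower.

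19 of 24 Treg core genes were higher in tumour Treg arrays (20 adjusted over the list alone, median 1.99, adjusted p = 1.25e-17). Of the conventional T genes, 10 of 11 were lower and 1 was higher (also adjusted over the list alone, median -2.07, adjusted p = 6.92e-10), and 12 of 13 naive and lymphoid homing genes were lower (12 adjusted over the list alone, median -2.11, adjusted p = 1.33e-13). Named examples were Il2ra (4.25), Tnfrsf9 (3.39) and Itgae (3.72) on the higher side, and Il2 (-4.12), Bach2 (-3.76) and Satb1 (-2.84) on the lower side. Each of these 3 lists had adjusted p = 0.0294 with an estimated correlation and kept its call, while the other 11 did not. The conventional T and the naive and lymphoid homing lists share genes such as Satb1, Tcf7 and Lef1, so they are not separate evidence. Effector Treg genes had 17 higher and 0 lower of 22 (18 and 0 adjusted over the list alone, median 1.56, adjusted p = 4.29e-14), including Ccr8 (2.82), Gzmb (2.71) and Il10 (2.14). Inhibitory receptors had 5 higher and 1 lower of 9 (7 and 1 adjusted over the list alone, median 0.99, adjusted p = 5.89e-04). Both had adjusted p = 0.118 with an estimated correlation. Glycolysis and hypoxia genes had 17 higher and 1 lower of 21 (18 and 1 adjusted over the list alone, median 0.84, adjusted p = 2.44e-09, adjusted p = 0.174 with an estimated correlation). They included Ddit4 (2.2), Bnip3 (1.62) and the enzymes Tpi1 (1.42) and Pgk1 (1.19). Cell cycle genes had 23 higher and 0 lower of 32 (the same adjusted over the list alone, median 0.82, adjusted p = 2.59e-12, adjusted p = 0.127 with an estimated correlation). Ccnb2 was higher by 2.57, Birc5 by 1.67 and Mki67 by 1.51. Costimulatory TNF receptors had 5 higher and 3 lower of 9 (also adjusted over the list alone, median 1.59, adjusted p = 0.0274, adjusted p = 0.315 with an estimated correlation).

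On the lower side, interferon response genes had 8 lower and 2 higher of 18 (also adjusted over the list alone, median -0.20, adjusted p = 0.0152, adjusted p = 0.543 with an estimated correlation), with Oasl2 at -1.65 and Mx1 at -0.82. Early T cell receptor response genes had 7 lower and 2 higher of 16 (7 and 3 adjusted over the list alone, adjusted p = 0.0403, adjusted p = 0.446 with an estimated correlation), with Fosb at -1.41 and Fos at -1.16. With the replicate number as a block this call ended (adjusted p = 0.07), while the uncalled Th2 list passed (adjusted p = 0.0354 in place of 0.0518). Heat shock and stress genes had 6 lower and 1 higher of 12 (also adjusted over the list alone, median -0.41, adjusted p = 0.0152, adjusted p = 0.474 with an estimated correlation). Cytotoxic effector genes had 6 lower and 2 higher of 11 (6 and 4 adjusted over the list alone, adjusted p = 0.0263, adjusted p = 0.315 with an estimated correlation), with Gzmk (-4.12) and Klrk1 (-3.48) lower and Gzmb higher. Markers of other cells moved beside these groups. Cd8a (-1.14) and Cd8b1 (-1.78), the chains of the CD8 coreceptor, were both lower in Treg arrays (2 of 2 adjusted over the list alone, adjusted p = 0.0274, adjusted p = 0.315 with an estimated correlation). B cell markers had 4 lower and 1 higher of 12 (also adjusted over the list alone, median -0.12, adjusted p = 0.0263, adjusted p = 0.372 with an estimated correlation). The lower B cell members included the class II antigen presentation genes H2-Aa (-4.23), H2-Ab1 (-3.22) and H2-Eb1 (-2.84). Macrophage and dendritic cell markers had 4 lower and 1 higher of 15 (also adjusted over the list alone, adjusted p = 0.828): Tyrobp, Fcer1g (-2.66), Cd68 (-2.40) and Itgax (-2.18) were lower, while the list's median was 0.52 and its mean -0.33. A list of plasmacytoid dendritic cell genes, written after the tumour values were seen, had 10 lower and 0 higher of 12 (median -3.40, adjusted p = 9.52e-10, adjusted p = 0.303 with an estimated correlation). Melanoma markers did not separate the cell types (1 higher of 9, also adjusted over the list alone, adjusted p = 0.326), with Dct at 0.28. The 14 uncalled lists had adjusted p from 0.0518 to 0.852, and among them the Polycomb list also had a median and mean of opposite sign. In all 3375 of 13231 genes passed, 1851 higher and 1524 lower, 760 of them at least 2-fold (4679 at an unadjusted p under 0.05).

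**Figure D2:**
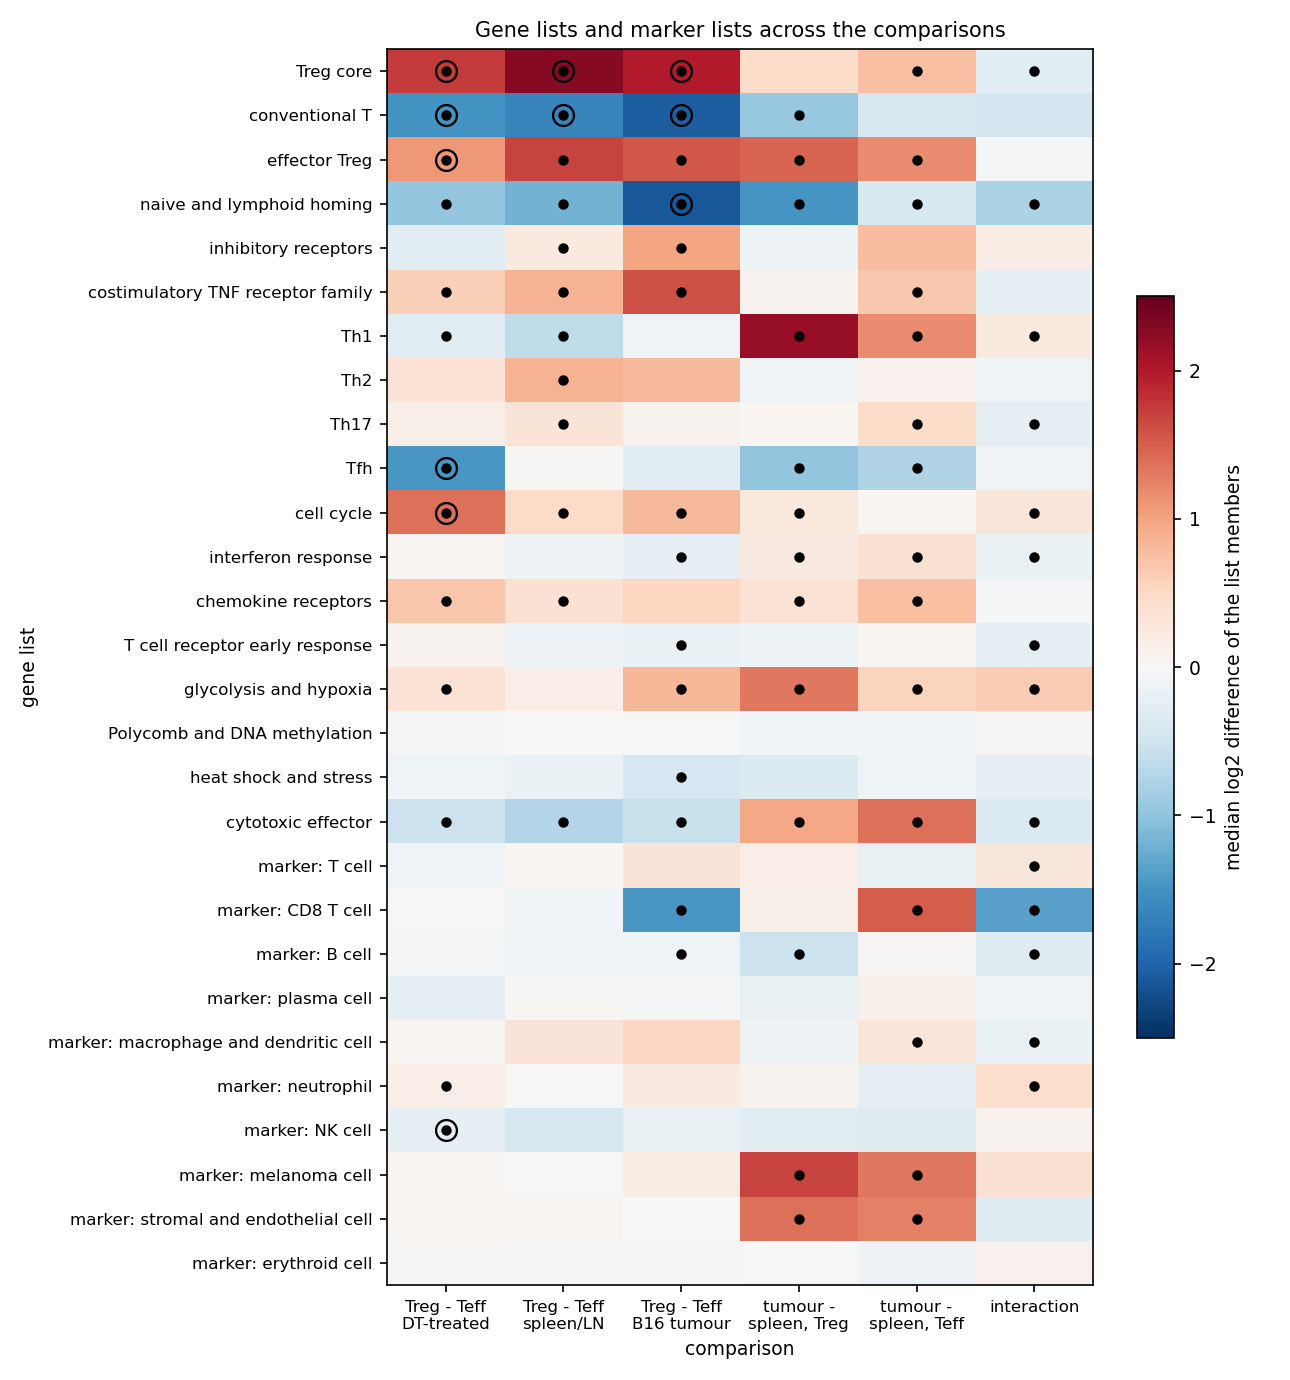
Median log2 difference (colour) of the members of 28 gene and marker lists (y axis) in the 6 comparisons (x axis); dots mark lists with a camera adjusted p under 0.05 and rings those also called with an estimated correlation. Treg core medians were 1.74, 2.28 and 1.99 in the 3 Treg against Teff comparisons, and melanoma marker medians were 1.68 and 1.32 in tumour against spleen.

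The 3 Treg against Teff comparisons share no arrays, and their calls overlapped over the 13231 genes on both kinds of array. DT-treated mice and spleen shared 444 higher genes, where 77.9 would be shared by independent lists, and 340 lower genes (44 if independent), with 10 and 12 genes called in opposite directions. DT-treated mice and tumour shared 639 higher (146 if independent) and 417 lower genes (79.1 if independent), with 31 and 30 opposite. Spleen and tumour shared 681 higher (138 if independent) and 563 lower genes (97.6 if independent), with 19 and 25 opposite. The spleen and tumour comparisons came from the same fit with a shared estimate of the spread, which can by itself raise their overlap. Dim genes were also seldom called: with the filter on them, 1895 of 6616 genes were called in spleen and 3190 of 6616 in the tumour. Taken over all 13231 genes, the numbers for independent lists given here are therefore too low for every pair and for all 3 settings. 373 genes were higher in all 3 settings (10.9 if independent) and 275 were lower in all 3 (5.07 if independent). Il2ra, Klrg1, Ctla4, Itgae, Tnfrsf9, Ccr8 and Il10 were among the former, and Il2, Gzmk, Klrd1, Tnfsf8 and Eomes among the latter. The log2 differences correlated across genes with Pearson's r of 0.618 for DT-treated mice and spleen, 0.546 for DT-treated mice and tumour and 0.658 for spleen and tumour (Spearman's rho 0.45, 0.481 and 0.544); genes are not independent replicates.

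Tumour Treg arrays were next set against Treg arrays from spleen and lymph node, to ask how Treg cells of a tumour differ from those of lymphoid tissue. Cxcr6 (1425832_a_at), a receptor of T cells resident in tissues, read 10.64 ± 0.571 (SD, n = 2) against 5.22 ± 0.455 (SD, n = 2), a log2 difference of 5.43 (SE 0.285, adjusted p = 1.09e-05). Ctla2a (1448471_a_at), a protease inhibitor, was higher by 4.88 (SE 0.118, adjusted p = 2.43e-07). Gpr83 (1423415_at) read 5.16 ± 0.057 (SD, n = 2) against 10.07 ± 0.064 (SD, n = 2) and was lower, at -4.91 (SE 0.151, adjusted p = 9.45e-07). Bach2 (1437667_a_at), a repressor of effector differentiation, differed by -3.23 (SE 0.0912, adjusted p = 6.14e-07) and Tcf7 by -3.09 (SE 0.105, adjusted p = 1.17e-06). Foxp3 differed by -6.72. The tissues also differed in sex-linked genes, with Xist (1427262_at) at -8.58 and the Y-linked Ddx3y (1426438_at) at 7.26, Eif2s3y at 6.96 and Kdm5d at 5.44, so tissue and sex of the mice cannot be told apart.

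Th1 genes had 11 higher and 0 lower of 15 (the same adjusted over the list alone, median 2.18, adjusted p = 2.5e-10), with the chemokines Ccl3 (4.19) and Ccl5 (2.60) and with Nkg7 (3.64). Glycolysis and hypoxia genes had 16 higher and 0 lower of 21 (17 and 0 adjusted over the list alone, median 1.31, adjusted p = 7.75e-14), such as Bnip3 (2.57), Ddit4 (2.01) and Tpi1 (2.0). Effector Treg genes had 16 higher and 0 lower of 22 (16 and 1 adjusted over the list alone, median 1.46, adjusted p = 7.42e-12), including Gzmb (3.68), Ccr2 (2.61), Areg (2.55) and Klrg1 (2.04). Cytotoxic effector genes had 7 higher and 0 lower of 11 (the same adjusted over the list alone, median 0.97, adjusted p = 3.86e-05). Naive and lymphoid homing genes had 11 lower and 0 higher of 13 (the same adjusted over the list alone, median -1.47, adjusted p = 1.36e-09), with Klf3 at -2.83. Conventional T genes had 6 lower and 1 higher of 11 (the same adjusted over the list alone, median -0.95, adjusted p = 0.00714). These 6 lists each had adjusted p = 0.158 with an estimated correlation, and none of the 13 called lists kept its call there. Tfh genes had 6 lower and 2 higher of 10 (the same adjusted over the list alone, median -0.99, adjusted p = 0.0103, adjusted p = 0.392 with an estimated correlation). Cxcr5, the follicular homing receptor, differed by -3.84 and Pdcd1 by 2.49. Cell cycle genes had 13 higher and 2 lower of 32 (14 and 3 adjusted over the list alone, median 0.26, adjusted p = 6.2e-04, adjusted p = 0.393 with an estimated correlation). Interferon response genes had 6 higher and 2 lower of 18 (8 and 3 adjusted over the list alone, median 0.22, adjusted p = 0.0243, adjusted p = 0.584 with an estimated correlation).

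Chemokine receptors had 7 higher and 3 lower of 14 (the same adjusted over the list alone, adjusted p = 0.0243, adjusted p = 0.208 with an estimated correlation), with Ccr1 (3.92) beside Cxcr6 on the higher side and Ccr9 (-3.30) beside Cxcr5 on the lower. Treg core genes split, with 12 higher and 6 lower of 24 (13 and 6 adjusted over the list alone, adjusted p = 0.062, not called). Tnfrsf9 (1.48) and Tnfrsf18 (1.13) rose while Foxp3 and Gpr83 fell, and the list's median was 0.47 but its mean -0.17. That mean includes Foxp3 at -6.72, and the list was not tested without it. Markers of tumour tissue moved with the tumour. Genes higher in tumour arrays, such as those of the glycolysis and hypoxia list, can therefore not be assigned to the Treg cells alone. Melanoma markers had 7 higher and 0 lower of 9 (the same adjusted over the list alone, median 1.68, adjusted p = 1.32e-05, adjusted p = 0.236 with an estimated correlation). The pigment enzyme Dct (1418028_at) read 9.99 ± 0.332 (SD, n = 2) against 3.66 ± 0.24 (SD, n = 2). Stromal and endothelial markers had 8 higher and 0 lower of 10 (9 and 1 adjusted over the list alone, median 1.37, adjusted p = 4.03e-04, adjusted p = 0.451 with an estimated correlation), with Sparc, a matrix protein, at 3.23. B cell markers had 5 lower and 0 higher of 12 (the same adjusted over the list alone, median -0.54, adjusted p = 0.0485, adjusted p = 0.46 with an estimated correlation), with Cd22 at -1.74, and were not called with the replicate number as a block (adjusted p = 0.0556). T cell markers had 0 of 8 passing (0 adjusted over the list alone, median 0.17, adjusted p = 0.237), with Cd3e at -0.23. The Polycomb list (2 higher and 3 lower of 17, or 2 and 4 adjusted over the list alone, adjusted p = 0.486) was among the 15 not called (adjusted p from 0.062 to 0.935); the inhibitory receptor and Th2 lists, also uncalled, had a median below and a mean above 0. In all 3123 of 13231 genes passed, 1506 higher and 1617 lower in the tumour, 682 of them at least 2-fold (4617 at an unadjusted p under 0.05). The count was 2010 without tumour Treg array 1.

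**Figure D3:**
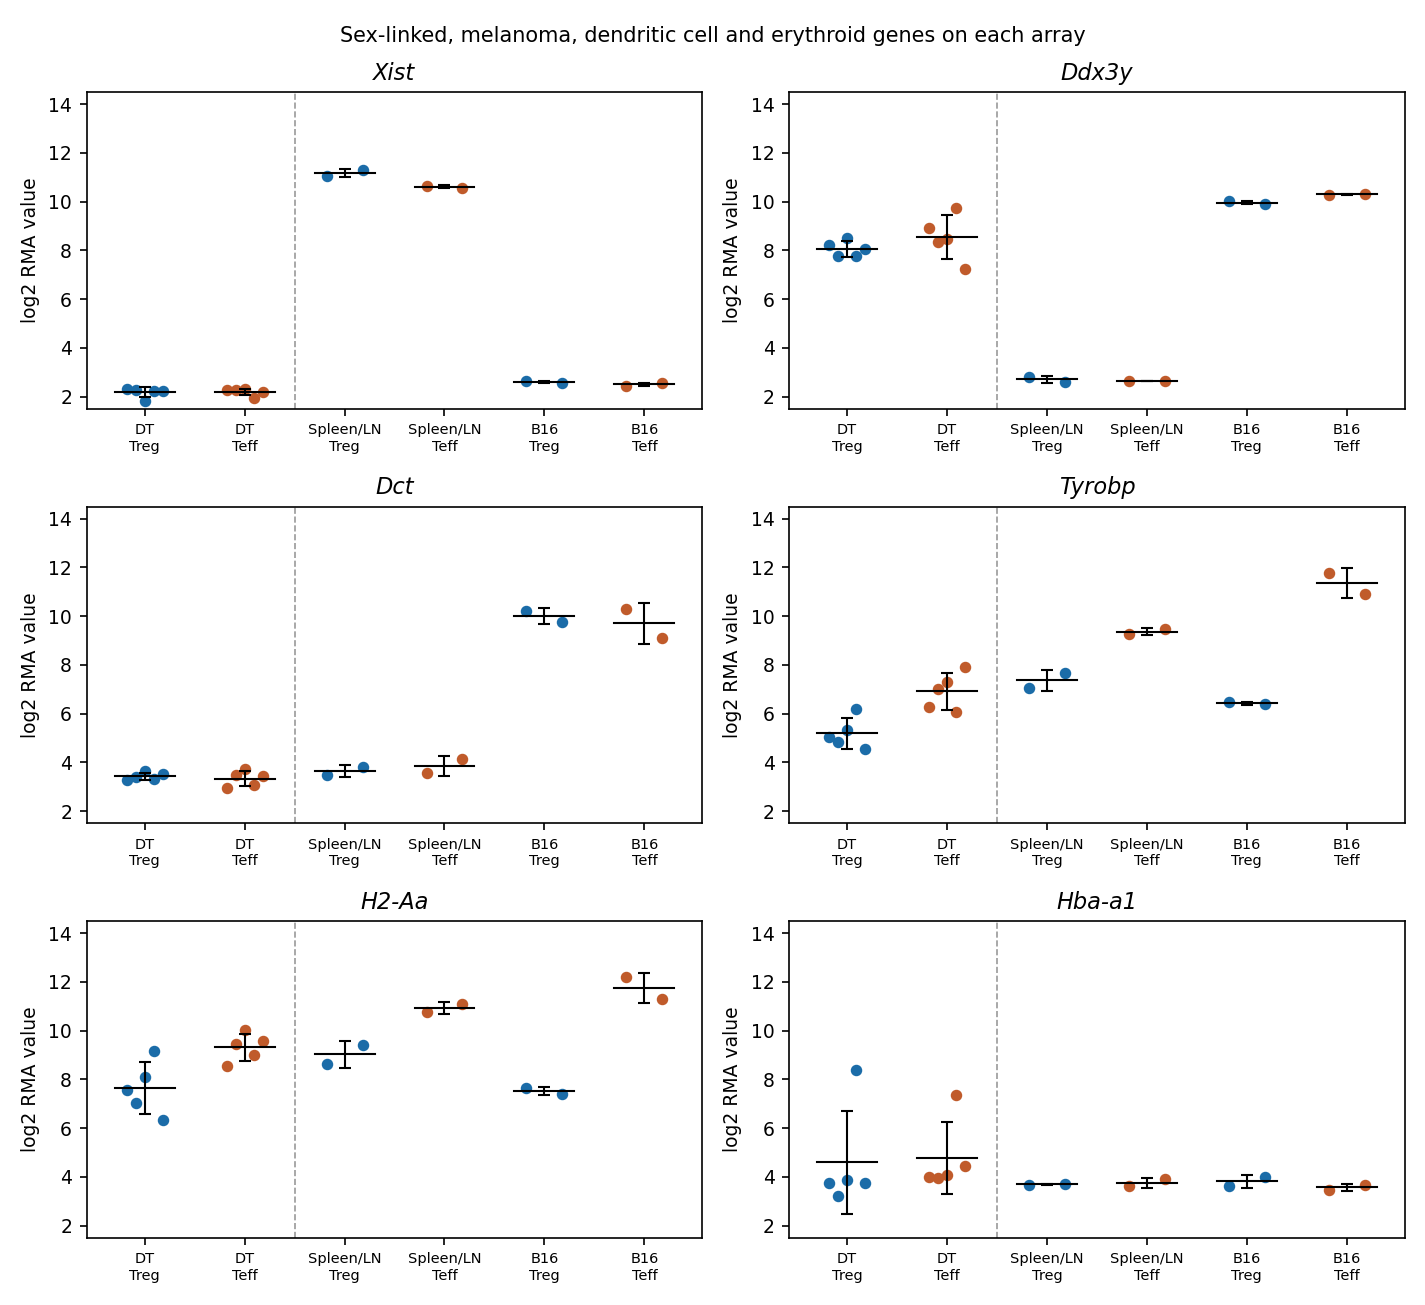
Log2 RMA values (y axis) of Xist, Ddx3y, Dct, Tyrobp, H2-Aa and Hba-a1 on each array, by group (x axis); points are arrays, horizontal lines group means, bars the SD, and the dashed line parts the separately normalized tables. Dct had means of 9.99 and 9.71 in the tumour groups and of 3.66 and 3.85 in the spleen and lymph node groups, and Hba-a1 read 8.37 and 7.37 on the DT arrays numbered 4. Xist was read by another probe set in the DT arrays than in the others.

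The same tissue contrast in Teff arrays asked how Foxp3-negative CD4 cells of the tumour differ from those of spleen and lymph node. Gzmb (1419060_at) read 9.28 ± 0.145 (SD, n = 2) against 5.57 ± 0.011 (SD, n = 2), a log2 difference of 3.72 (SE 0.14, adjusted p = 5.28e-06). Fgl2 (1421855_at), a secreted fibrinogen-like protein, was higher by 3.39 (SE 0.0837, adjusted p = 4.05e-07). Sostdc1 (1449340_at) read 4.37 ± 0.447 (SD, n = 2) against 9.43 ± 0.253 (SD, n = 2) and was lower, at -5.05 (SE 0.197, adjusted p = 5.28e-06). Pou2af1 (1416957_at), a transcriptional coactivator of lymphocytes, differed by -3.63 (SE 0.122, adjusted p = 3.94e-06) and the cytokines Il21 and Il4 by -2.97 and -2.20. Xist (-8.11) and Ddx3y (7.65) differed here as in Treg arrays, so the confounding of sex with tissue holds for these groups too. Foxp3 differed by 0.034 (adjusted p = 0.854). Its probe set read only 3.25 in tumour Treg arrays too, so this value cannot tell whether Treg cells were among the tumour Teff cells.

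Cytotoxic effector genes had 10 higher and 1 lower of 11 (the same adjusted over the list alone, median 1.38, adjusted p = 7.64e-11), with Gzmb, the activating receptor Klrk1 (2.95), Serpinb9 (1.88) and Fasl (1.57). Effector Treg genes, in these cells sorted as Foxp3-negative, had 17 higher and 0 lower of 22 (17 and 1 adjusted over the list alone, median 1.18, adjusted p = 2.43e-17), such as Fgl2, Ccr2 (2.95) and Lgals3 (2.58). Treg core genes had 15 higher and 5 lower of 24 (16 and 5 adjusted over the list alone, median 0.76, adjusted p = 1.22e-06). Chemokine receptors had 8 higher and 2 lower of 14 (9 and 2 adjusted over the list alone, median 0.75, adjusted p = 1.6e-04), with Cxcr6 (2.86) higher and Cxcr5 (-2.87) lower. Th17 genes had 4 higher and 0 lower of 7 (the same adjusted over the list alone, median 0.46, adjusted p = 3.53e-04), with the nuclear receptors Rora (2.18) and Ahr (1.87). Each of these 5 lists had adjusted p = 0.0943 with an estimated correlation, the lowest of the 15 called lists, so none kept its call. Th1 genes had 12 higher and 0 lower of 15 (13 and 0 adjusted over the list alone, median 1.18, adjusted p = 1.29e-11, adjusted p = 0.12 with an estimated correlation), with Ccl4 (2.27) and Il18rap (2.13). Glycolysis and hypoxia genes had 12 higher and 1 lower of 21 (14 and 1 adjusted over the list alone, median 0.55, adjusted p = 4.41e-09, adjusted p = 0.14 with an estimated correlation), among them Bnip3 (1.5), Tpi1 (1.43) and the hexokinase Hk2 (0.98). Interferon response genes had 9 higher and 0 lower of 18 (10 and 1 adjusted over the list alone, median 0.39, adjusted p = 1.09e-05, adjusted p = 0.262 with an estimated correlation), with Mx1 (1.34) and Ifit3 (1.22). Costimulatory TNF receptors had 5 higher and 1 lower of 9 (5 and 2 adjusted over the list alone, adjusted p = 0.0254, adjusted p = 0.224 with an estimated correlation).

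Lower in tumour Teff arrays were naive and lymphoid homing genes, 7 of 13 with 1 higher (8 and 1 adjusted over the list alone, median -0.40, adjusted p = 5.44e-04, adjusted p = 0.14 with an estimated correlation), for example Igfbp4 (-1.39), Actn1 (-1.13) and Lef1 (-0.93). Tfh genes had 7 lower and 2 higher of 10 (8 and 2 adjusted over the list alone, median -0.76, adjusted p = 0.0017, adjusted p = 0.224 with an estimated correlation), with Il21 and Cxcr5. Cell cycle genes were not called, with 2 higher and 4 lower of 32 (2 and 6 adjusted over the list alone, adjusted p = 0.529). Melanoma markers had 7 higher and 0 lower of 9 (the same adjusted over the list alone, median 1.32, adjusted p = 2.64e-07, adjusted p = 0.14 with an estimated correlation), with Dct at 5.86. Stromal and endothelial markers had 8 higher and 0 lower of 10 (the same adjusted over the list alone, median 1.26, adjusted p = 1.52e-06, adjusted p = 0.224 with an estimated correlation), with Sparc at 3.95. As in Treg arrays, genes higher in the tumour can therefore not be assigned to the T cells alone. Both CD8 chains were higher (2 of 2 adjusted over the list alone, median 1.51, adjusted p = 0.00557, adjusted p = 0.224 with an estimated correlation), with Cd8b1 at 1.80. The call of Cd8a ended without spleen Teff array 2 (adjusted p = 0.0508, the highest over its alternatives, the lowest being 3.32e-04). Macrophage and dendritic cell markers had 5 higher and 2 lower of 15 (6 and 2 adjusted over the list alone, median 0.30, adjusted p = 0.0331, adjusted p = 0.585 with an estimated correlation), with Tyrobp at 2.0. The plasmacytoid dendritic cell genes, listed after the tumour values were seen, had 10 higher and 0 lower of 12 (median 1.98, adjusted p = 2.11e-09, adjusted p = 0.218 with an estimated correlation). The 13 uncalled lists had adjusted p from 0.0745 to 0.953, among them the early T cell receptor response and plasma cell lists, whose medians were above and means below 0. In all 2091 of 13231 genes passed, 1006 higher and 1085 lower, but 337 of the 415 that differed at least 2-fold were higher (3845 at an unadjusted p under 0.05). The count was 1362 without tumour Teff array 1, 1006 without spleen Teff array 1 and 970 without spleen Teff array 2. The Treg and Teff tissue comparisons share no arrays and had 590 higher genes in common (115 if independent) and 636 lower genes (133 if independent), with 34 and 33 opposite. These comparisons came from the same fit with a shared estimate of the spread, and both carry the sex difference. Each of these can raise the overlap above that of independent lists. The numbers for independent lists are also too low here, since they count dim genes that were seldom called. The log2 differences of these comparisons correlated with Pearson's r of 0.639 and Spearman's rho of 0.506 across genes, which are not independent replicates.

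Whether the tumour difference itself differed between Treg and Teff was tested as an interaction, and each value below 0 means a tumour minus spleen difference that was lower in Treg arrays. Bach2 (1437667_a_at) and Tcf7 (1433471_at) differed by -2.77 (SE 0.129, adjusted p = 8.8e-05) and -2.70 (SE 0.149, adjusted p = 1.93e-04), Gpr83 by -4.01 (SE 0.214, adjusted p = 1.92e-04) and Foxp3 by -6.75 (SE 0.125, adjusted p = 1.59e-07). Havcr2 (1451584_at) had an interaction of 3.29 (SE 0.326, adjusted p = 0.00174), from tumour minus spleen differences of 4.07 in Treg and 0.78 in Teff arrays. The chemokine receptor Ccr1 (1419609_at) had 3.30 (SE 0.351, adjusted p = 0.00215) and Spp1 (1449254_at) 4.74 (SE 0.562, adjusted p = 0.00307). Ccr9 had -5.87, from tissue differences of -3.30 in Treg and 2.57 in Teff arrays (the latter with adjusted p = 0.0124, with a range of 0.00101 to 0.0834 over its alternatives). The call of Ccr9 in Teff arrays ended without tumour Teff array 1 (adjusted p = 0.0714) and without spleen Teff array 1 or 2 (0.0701 and 0.0671). Tyrobp had -2.94, from -0.94 and 2.0. The plasmacytoid dendritic cell genes also had 6 lower and 0 higher of 12 (median -2.10, adjusted p = 1.3e-08, adjusted p = 0.365 with an estimated correlation).

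Naive and lymphoid homing genes had 6 with a lower difference in Treg and 0 with a higher one of 13 (8 and 1 adjusted over the list alone, median -0.78, adjusted p = 3.22e-08, adjusted p = 0.221 with an estimated correlation), with Klf3 (-2.37) beside Tcf7 and Bach2. Glycolysis and hypoxia genes had 7 higher and 0 lower of 21 (14 and 1 adjusted over the list alone, median 0.63, adjusted p = 1.41e-08), such as Ddit4 (1.96), Pkm (1.21) and Eno1 (1.03). Treg core genes had 2 higher and 4 lower of 24 (4 and 8 adjusted over the list alone, median -0.29, adjusted p = 0.00209). The 4 lower genes were Foxp3 (-6.75), Gpr83 (-4.01), Socs2 (-1.60) and Nrp1 (-1.32). The list was not tested without Foxp3, whose low reading in tumour Treg arrays is unexplained. Th17 genes had 2 lower of 7 (2 adjusted over the list alone, adjusted p = 0.0169), with Ahr at -1.82. These 3 lists had adjusted p = 0.308 with an estimated correlation. Th1 genes had 5 higher and 0 lower of 15 (7 and 0 adjusted over the list alone, median 0.24, adjusted p = 0.0104, adjusted p = 0.45 with an estimated correlation), with Ccl3 (2.72), Nkg7 (2.21) and Ccl5 (1.44). Cell cycle genes had 3 higher of 32 (5 adjusted over the list alone, median 0.30, adjusted p = 0.00209), with Ccnb2 (1.64) and Cenpe (1.13). Early T cell receptor response genes had 2 lower of 16 (4 adjusted over the list alone, median -0.25, adjusted p = 0.0104), Fos (-1.05) and Fosb (-1.23). Cytotoxic effector genes had 2 higher and 5 lower of 11 (the same adjusted over the list alone, adjusted p = 0.04), with Prf1 (1.52) and Klrk1 (-2.76). B cell markers had 2 lower of 12 (2 adjusted over the list alone, adjusted p = 0.0159) and CD8 markers 1 lower of 2 (2 adjusted over the list alone, adjusted p = 0.0175). Each of these 5 lists had adjusted p = 0.382 with an estimated correlation. The interferon (median -0.17, adjusted p = 0.0437) and macrophage and dendritic cell lists (median -0.17, adjusted p = 0.0496) had 2 lower each (4 of 18, and 3 of 15 with 1 higher, adjusted over the list alone). Both had adjusted p = 0.658 with an estimated correlation, and the interferon list had 0.0667 with the replicate number as a block. T cell markers (0 of 8 passing, also adjusted over the list alone, median 0.29, adjusted p = 0.04, adjusted p = 0.62 with an estimated correlation) and neutrophil markers (1 higher of 8, or 2 adjusted over the list alone, adjusted p = 0.0402, adjusted p = 0.379 with an estimated correlation) completed the 14 called lists. The other 14 had adjusted p from 0.0608 to 0.948, and the Tfh and plasma cell lists among them had a median below and a mean above 0. In all 768 of 13231 genes passed, 374 higher and 394 lower, 351 of them at least 2-fold (2538 at an unadjusted p under 0.05). The count was 434 and 508 without tumour Treg arrays 1 and 2, 406 and 355 without spleen Teff arrays 1 and 2, and 447 without spleen Treg array 2.

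**Figure D4:**
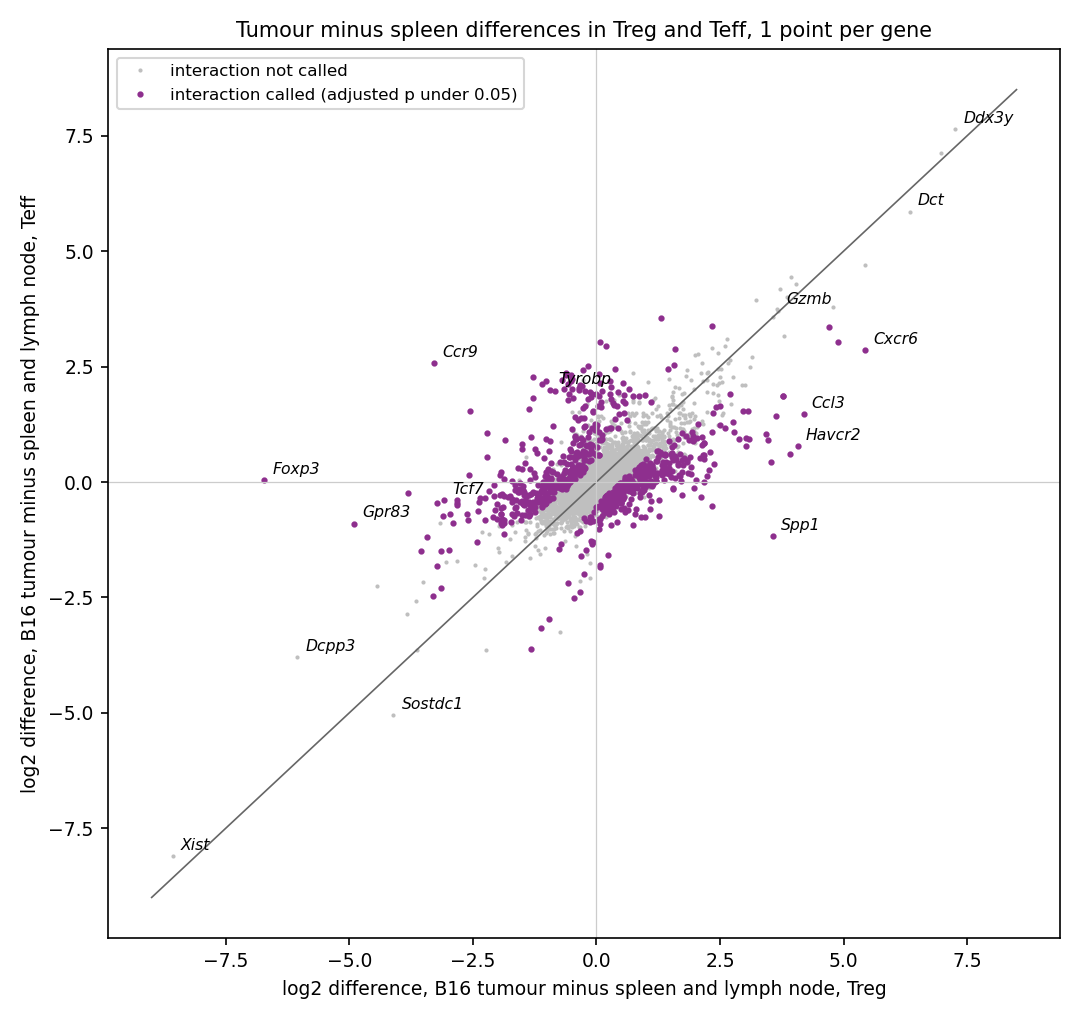
Tumour minus spleen log2 difference of each gene in Treg (x axis) against that in Teff arrays (y axis); grey points are genes whose interaction was not called, purple points the 768 called genes, and the diagonal marks equal differences. Foxp3 (-6.72 and 0.034) and Gpr83 lie far from the diagonal, while Xist (-8.58 and -8.11), Ddx3y (7.26 and 7.65) and Dct (6.34 and 5.86) lie near it.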

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

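The tests of the explanations in this part were chosen only after the patterns were seen, and for the plasmacytoid dendritic cell list alone the prediction was written before its own result. A different split of the 10 arrays from DT-treated mice gave at most 679 called genes, against 2187 for Treg against Teff. Of 100 splits drawn from 126, 1, the real one, reached that number, which is the lowest share this test can give. Chance is thus an unlikely source of the count, but is not excluded by a test that treats the arrays as unlinked.

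Foxp3 was at the Teff level on arrays labelled Treg from DT-treated mice and from the tumour. Against arrays without Treg cells, by a wrong label or a failed sort, the other Treg core genes were counted. Of 23, 20 were called higher in DT-treated mice and 19 in the tumour. But 15 of 24 Treg core genes were also higher in tumour than in spleen Teff arrays, which are both labelled Teff. Such a count therefore cannot by itself show Treg cells, though the list's median was larger in the Treg against Teff contrasts (1.74 and 1.99, against 0.76). A reporter transcript that the Foxp3 probe set does not read could leave the difference at 0.025 in DT-treated mice, and no other group there has that strain label, so this stays open; for the tumour it is argued against by the difference of 6.85 in spleen and lymph node, if the shared strain label holds. Less Foxp3 RNA in tumour Treg cells may also give the tumour minus spleen difference of -6.72, and no value here decides it. The tumour Treg arrays with low Foxp3 also have Y-linked RNA and low Xist. So do the DT Treg arrays, with Ddx3y at least 7.755 and Xist, read by another probe set, at most 2.305. The spleen Treg arrays, with high Foxp3, have high Xist. Spleen Teff arrays have low Foxp3 with high Xist, but they were sorted as Foxp3-negative and so do not bear on this. A strain or allele other than the one on the label was not tested and stays open for the tumour.

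Tyrobp, Fcer1g, Cd68, Itgax, H2-Aa, H2-Ab1 and H2-Eb1, of the B cell and the macrophage and dendritic cell lists, were higher in tumour Teff than in tumour Treg arrays. The latter list was not called (adjusted p = 0.828), and the former had adjusted p = 0.372 with an estimated correlation. In DT-treated mice Tyrobp was also higher in Teff arrays, as were, with calls that ended without single arrays, Fcer1g and H2-Aa. In spleen and lymph node Tyrobp read 9.25 and 9.47 in Teff against 7.05 and 7.68 in Treg arrays. H2-Aa read 10.76 and 11.11 there against 8.64 and 9.43. Macrophages as the source are argued against by a median difference (Treg minus Teff) of 0.816 over 6 macrophage genes (0.52 to 1.33), and B cells by -0.0248 over 6 B cell genes (-0.106 to 0.645). Plasmacytoid dendritic cells among the Foxp3-negative cells are a candidate source: 10 of 12 measured genes of their list were lower in Treg, 10 of 12 higher in tumour Teff than in spleen Teff, and in tumour Teff against Treg arrays Cox6a2 read 9.38 against 5.82, Tcf4 9.89 against 6.01 and Spib 9.08 against 4.37. CD4 beads would keep such cells, while the GFP gate would remove them from the Treg sort, and 5 of the 12 genes lay above the median gene in tumour Treg arrays. A change within Teff cells was not tested and stays open. Ccr9, Mpeg1, Ly6d and Cdh1 were also higher in tumour Teff than in tumour Treg arrays. Whether they share this source was not tested, so their differences cannot be assigned to T cells.

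Naive and lymphoid homing genes were lower in tumour than in spleen Treg arrays (11 of 13, adjusted p = 0.158 with an estimated correlation), and 6 of 13 more so than in Teff arrays (adjusted p = 0.221 with an estimated correlation). Dilution of T cell RNA by RNA of melanoma and stromal cells, whose markers were higher in the tumour, would lower all T cell genes, but 8 T cell markers had a median difference of 0.169 (-0.23 to 0.293) against -1.47 for the 13 homing genes. The sex of the mice, with Xist at -8.58 in the same comparison, cannot be told apart from the tissue. A response of Treg cells to the tumour, or entry of cells already low in these genes, may account for the pattern and was not tested.

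The tumour difference differed between Treg and Teff for 768 genes by the interaction test, and plasmacytoid dendritic cell genes moved with the values below 0 (6 of 12 lower, median -2.10, adjusted p = 0.365 with an estimated correlation). Values above 0 were Spp1 4.74, Ccr1 3.30, Havcr2 3.29, Pcsk1 2.85, Ccl3 2.72, Cxcr6 2.57, Nkg7 2.21, Ddit4 1.96, Ccnb2 1.64, Prf1 1.52, Ccl5 1.44, Tbx21 1.32, Pkm 1.21, Cenpe 1.13 and Eno1 1.03. Values below 0 were Foxp3 -6.75, Ccr9 -5.87, Chdh -4.11, Gpr83 -4.01, Gbp2b -3.57, D13Ertd608e -3.56, Tyrobp -2.94, Bach2 -2.77, Klrk1 -2.76, Tcf7 -2.70, Klf3 -2.37, H2-Aa -2.33, Cd68 -1.95, Ahr -1.82, Klrd1 -1.64, Il2 -1.61, Socs2 -1.60, Cd8b1 -1.51, Nrp1 -1.32, Fosb -1.23, Fos -1.05, Ccr6 -1.0, Gbp2 -0.78 and Mx1 -0.71. 9 of these calls ended when 1 array was left out. Removal of any 1 of 6 arrays did so for Cd8b1, Cd68, Tbx21 and Ccr6, of 7 for Mx1 and Gbp2, of 5 for H2-Aa and of 4 for Il2, and of 1 for Klrd1. The highest adjusted p was then 0.15 for Cd8b1, 0.131 for Mx1 and 0.0932 for H2-Aa (without spleen Teff array 1), 0.149 for Cd68, 0.155 for Gbp2, 0.107 for Tbx21, 0.0763 for Il2 and 0.0509 for Klrd1 (without spleen Teff array 2), and 0.0972 for Ccr6 (without tumour Treg array 1). The lowest over all alternatives ran from 7.52e-04 for Cd8b1 to 0.0105 for Mx1.

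Single arrays stood apart from the other 4 of their group for 11 of 144 gene and group values tested (7.64%), where chance picks out about 1 in 20. Hba-a1 read 8.37 in DT Treg array 4 and 7.37 in DT Teff array 4. Treg array 4 also stood apart for Pdcd1 (6.40) and Uhrf1 (9.78), Teff array 4 for Zbp1 (8.66), and Teff array 5 for Mmp9 (4.36) and Pde3b (9.5). The others were Tdrp (4.18) and Cd4 (7.94) in Treg array 2, P4ha1 (8.40) in Treg array 3 and Egr3 (8.75) in Teff array 1.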

How the results depend on the processing

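Of 5394 values of named genes under alternatives, 5237 kept their direction and side of the threshold, 148 were weaker (111 of them by leaving out 1 array), 9 stronger and 0 reversed. Counted per comparison, so that a gene can count more than once, 287 of 323 calls of named genes held under all of their alternatives. Where nothing else is said, the cause was not tested. In DT-treated mice 2187 genes became 3798 with array weights, and, in alternatives chosen after seeing the data, 2367 without the arrays numbered 4 and 3644 without these and Teff array 5. Testing all probe sets, with more features tested, gave 2809 for spleen, 5295 for tumour, 4900 for Treg and 3160 for Teff between tissues, and a trended robust prior gave 1162 for the interaction. Leaving out 1 array, with fewer arrays and a lone array assumed to vary like the other groups, gave 1580 to 3048 in DT-treated mice, 969 to 1257 in spleen, 2308 to 2650 in the tumour, 2010 to 2371 in Treg and 970 to 1479 in Teff between tissues, 355 to 742 for the interaction, and 0.413 to 0.984 for the permutation p of Foxp3. With an estimated correlation the called lists fell from 13 to 6, 12 to 2, 14 to 3, 13 to 0, 15 to 0 and 14 to 0. This setting also uses the few residual degrees of freedom of each fit. The conventional T list in spleen had an estimated correlation of -0.0649, below the preset 0.01, yet its adjusted p rose from 2.35e-14 to 0.016. The lost calls therefore do not show that list members were correlated. At adjusted p under 0.01, with fewer genes called, shared genes fell from 784 to 404, 1056 to 533, 1244 to 673 and, between tissues, 1226 to 590. With the number in the titles as a replicate block, 3242, 1695, 3198, 2938, 1860 and 698 genes and 11, 11, 14, 12, 15 and 13 lists were called, and within tissue 1828, 3364 and 736 genes (spleen, tumour, interaction). Deviations of same-numbered DT arrays correlated by 0.37, 0.39 and 0.50 for numbers 3, 4 and 5. Each exceeded the highest correlation of that Treg array with a Teff array of another number (-0.042, 0.17 and 0.11). For numbers 1 and 2 they correlated by 0.04 and 0.23, below that value (0.084 and 0.31). The correlation was 0.024 in spleen, 0.19 in the tumour, -0.025 in Treg and -0.078 in Teff arrays. The labels state no pairs, so the main fits have no block. A link between same-numbered DT arrays stays open, and the main fit ignores it. The series table could not replace the value table, since its Teff columns were not matched; its Treg values were identical. Renewed scaling moved the median of all genes by under 0.1. Signal over background limits dim genes: without scanner intensities or detection calls, a low value could not be told from background.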

Other observations

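The plasmacytoid dendritic cell list was tested after the other values, and the genes of the first 2 paragraphs were chosen after their values were seen, those of the first from the 373 higher and 275 lower genes shared by the 3 Treg against Teff comparisons. Further genes outside the lists were higher in Treg arrays of each setting. Log2 differences in DT-treated mice, spleen and tumour were 2.74, 2.79 and 3.43 for Itih5, a binder of hyaluronan, and 2.18, 2.39 and 2.38 for the laminin chain Lamc1. They were 1.74, 1.76 and 2.27 for the glutaredoxin Glrx, 1.74, 1.80 and 2.05 for the paraoxonase Pon3, and 1.72, 2.35 and 1.74 for the lipoxygenase Alox8. Arl5a (2.06, 1.80 and 2.56), Csrp2 (2.74, 1.71 and 2.34) and Ncmap (1.75, 3.33 and 2.64) were higher too. Lower in Treg arrays of each setting were the cytoskeletal adaptor Pdlim4 (-3.34, -4.28 and -2.99), the actin regulator Rflnb (-2.26, -2.49 and -3.41) and the membrane traffic gene Ehd3 (-2.35, -2.17 and -2.73). The sialyltransferases St3gal6 (-2.30, -2.53 and -2.61) and St8sia1 (-1.93, -1.81 and -2.57), and Tdrp (-4.41, -3.02 and -3.65), were lower as well.

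Some transcripts foreign to T cells varied between arrays of 1 group. Dcpp3 and PSP, secreted proteins of salivary glands, read 11.55 ± 1.24 and 7.92 ± 2.94 (SD, n = 2) in Treg arrays of spleen and lymph node, against 5.49 ± 0.16 and 3.48 ± 0.122 in tumour Treg arrays. The adjusted p of PSP was 0.0382 with all arrays and from 0.00631 to 0.169 over its alternatives. It was 0.168 without spleen Treg array 1, and 0.125 and 0.134 without tumour Treg arrays 1 and 2.

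The list of plasmacytoid dendritic cell genes, tested in all comparisons, had 0 higher and 10 lower of 12 in tumour Treg against Teff arrays (median -3.40, adjusted p = 9.52e-10; adjusted p = 0.303 with an estimated correlation). In spleen 0 were higher and 9 lower (median -1.22, adjusted p = 4.32e-05; adjusted p = 0.428 with an estimated correlation), and in DT-treated mice 1 was higher and 6 of 14 lower (median -0.55, adjusted p = 4.73e-04; adjusted p = 0.118 with an estimated correlation). Between tissues, Teff arrays had 10 higher and 0 lower in the tumour (median 1.98, adjusted p = 2.11e-09; adjusted p = 0.218 with an estimated correlation) and Treg arrays 2 higher and 2 lower (median -0.32, adjusted p = 0.805). The interaction had 6 lower (median -2.10, adjusted p = 1.3e-08; adjusted p = 0.365 with an estimated correlation). None of its 12 genes on the smaller array is in another list.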
